A study of Homo sapiens with 4 samples.

How the data were processed

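RNA was measured by Illumina sequencing of total RNA in 4 libraries from 2 human thyroid cancer cell lines. FTC-133 is a follicular thyroid carcinoma line and 8505C an anaplastic thyroid carcinoma line. Each line carried an empty vector or a vector for overexpression of CRABP1, cellular retinoic acid binding protein 1, and each of the 4 groups held 1 library. The labels state Trizol extraction and minimum values for RNA quality, and do not say whether libraries came from separate cultures.

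The authors deposited 1 table of TPM values, which are reads divided by gene length and scaled to the same total in each library, for 58884 Ensembl genes. Each column summed to 1000000. Per the submitters' processing notes, FastQC, Trimmomatic 0.38, featureCounts 2.0.0 and the GRCh38 build were used; the aligner, the annotation and any strand setting are not given in the sources used here. Without a stated strand setting, reads of a gene and an overlapping antisense gene cannot be told apart, and reads of near-identical copies, such as CGB5, PSG5, PSG6, PAGE1, PAGE2 and NPIPB6, are uncertain. Every column was assigned to its sample by name, and no 2 columns were identical.

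TPM values carry no total read number by themselves. Multiplied by the union exon length of GENCODE 29, which held 58611 of the identifiers, most low values fell on whole multiples of 1 step per library. Between 90.5% and 91.6% of values of up to 50 reads, and between 73.8% and 75.6% of all values above 0, were within 0.02 of a whole read. The steps gave about 20331453 reads for FTC-133 with vector, 20309210 for FTC-133 with CRABP1, 19174594 for 8505C with vector and 19304231 for 8505C with CRABP1. The 37 mitochondrially encoded genes held 28.6% and 25.9% of the TPM in FTC-133 and 26.4% and 25.9% in 8505C, with vector and CRABP1 in that order. These recovered reads served for 95% Clopper-Pearson intervals of a ratio of 2 libraries and for floors of 3 reads. Both cover counting error only. Reads also served for filters on read number, Poisson draws and tests on counting error, whereas limma and camera used TPM. Symbols came from a gene name table that held 58472 of the identifiers.

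Ratios were computed as log2 of TPM plus a pseudocount of 1, which understates the ratio of low genes, over genes with a mean of at least 1 TPM in the libraries compared. With 1 library per group there is no replicate error within a line, so genes were counted by a 2-fold rule and no p-value was computed for a line. Folds printed with an interval are plain TPM ratios. For 47 gene lists, the median ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins. A list stood apart below the percentile 2.5 or above 97.5, and lists with fewer than 5 measured members were left out. Over both lines, limma with a mean-variance trend was fitted with cell line and transfection as terms, which leaves 1 residual degree of freedom. In limma the lines then act as the replicates, and its p-values measure only the spread between these libraries. P-values were two-sided and adjusted by Benjamini-Hochberg at 0.05. Lists were tested with camera at a preset correlation of 0.01. At that preset a p-value rests on the spread among genes, not on the 2 lines as replicates. A small camera p-value is therefore not evidence from replicate libraries. Calculations used Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1, and R 4.3.3 with limma 3.58.1.

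The groups, tests, lists, thresholds, alternatives and the rule for naming genes were set before the data were examined. The rule took the 12 genes with the largest ratio each way per line, the 12 each way by the smaller ratio of both lines, 5 each way in opposite directions, and 12 each way between the lines. It passed over clones, pseudogenes and CRABP1. Applied as written, it named mostly short RNAs: 12, 11, 10 and 11 of the 12 genes in the lists for 8505C higher, 8505C lower, FTC-133 higher and FTC-133 lower had fewer than 20 reads. After their values were seen, the same ranking was therefore repeated among protein-coding genes with at least 20 reads over the libraries of a comparison, and the genes named below come from that repeat and from the lists. The alternatives were a pseudocount of 0.1, no filter, a mean of at least 5 TPM (also 30 TPM and a rank correlation where the lines were correlated), median-ratio scaling, a 1.5-fold threshold, removal of mitochondrially encoded genes, no trend, no term for the other factor, an estimated correlation and means in place of medians. Those added after seeing the data were the restriction to protein-coding genes with enough reads and the removal of trends on GC content and length, which were known for all 1074 list members.

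The limma step was tested on simulated data with 200 genes changed alike in both lines, in 5 draws per setting. For the sizes from 2-fold to 16-fold, 19187 to 19558 genes were fitted. At a dispersion of 0.01 and 1 size at a time, it recovered 0% of genes changed 2-fold in every draw, 0% to 83.5% of those changed 4-fold and 94.5% to 98% of those changed 16-fold, the last with 11 to 38 false calls. At a dispersion of 0.05 the ranges were 0%, 0% to 41.5% and 94.5% to 100%, the last with 13 to 79 false calls. The first simulation mixed 2-fold and 4-fold changes and recovered 0% of either. A mixture with 16-fold and 64-fold changes added recovered 10% to 34% of the 2-fold and 82% to 92% of the 4-fold genes at the lower dispersion, and 2% to 4% and 28% to 84% at the higher, so recovery of one size depended on the others present, and sizes were then simulated singly. With 64-fold changes alone, the fixed TPM total shifted unchanged genes by a median of -0.49 to -0.38 on the log2 scale and 4636 to 9137 of them were called at the lower dispersion. A gene that misses the limma threshold here is therefore not shown to be unchanged. Of 40 simulated lists of 25 genes, camera over 19518 genes with the preset correlation recovered 1 raised by 0.4 (adjusted p = 1.44e-14) and called 0 others; with an estimated correlation it missed the raised list (adjusted p = 0.998). The percentile rule, with 1000 random lists over 19587 genes simulated for FTC-133, marked 6% of 100 unchanged lists and 100% of lists shifted by 0.3. In both list simulations the genes varied independently, with a median estimated correlation of -0.013 for camera. Neither simulation therefore shows how often lists whose members vary together are called falsely. The 2-fold rule marked 44% of genes changed 2-fold and 95% of those changed 4-fold in FTC-133, and 42% and 97% in 8505C, over 100 genes of each size.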

Results

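The transcriptomes of FTC-133 and 8505C cells with an empty vector or with CRABP1 overexpression were compared in 4 libraries, 1 per group. The design addresses what CRABP1, a cytoplasmic carrier of retinoic acid, does to gene expression in thyroid cancer cells. About 20331453 and 20309210 reads lay behind the TPM values of FTC-133 with vector and with CRABP1, and 19174594 and 19304231 behind those of 8505C. No value within a line has a replicate, intervals cover counting error only, and genes are described as higher or lower between libraries unless a test over both lines was passed.

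CRABP1 (ENSG00000166426; GRCh38, chromosome 15, 78340324 to 78348230, plus strand, GENCODE 29) was listed at 0 TPM in both vector libraries. A count of 0 allows up to 0.555 TPM in FTC-133 and 0.594 TPM in 8505C, the level of 3 reads. With the overexpression vector it reached 385 TPM from about 2018 reads in FTC-133 and 537 TPM from about 2706 reads in 8505C. These levels were at least 694-fold and 905-fold higher than the vector floors, and ranked 227 and 176 among all genes of the libraries. The table used the length of the endogenous gene; a vector that carries part of the transcript would change the TPM for the same number of reads.

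In FTC-133, inflammatory genes were higher with CRABP1. CXCL8, a neutrophil chemokine, was at 203 TPM with vector and 1834 TPM with CRABP1, a ratio of 9.04 (95% interval 8.68 to 9.43). CSF2, a myeloid growth factor, was 8.78-fold higher (7.60 to 10.2), the soluble pattern receptor PTX3 6.79-fold (6.39 to 7.22) and IL6 5.65-fold (5.06 to 6.32). Besides CRABP1, the largest ratios among protein-coding genes with at least 20 reads were those of the membrane glycoprotein PDPN, at 1.09 and 46.1 TPM (42.3-fold, 27.8 to 67.8), and the proteoglycan BGN, at 0.764 and 28.2 TPM (36.9-fold, 20.2 to 79.2). MEOX2, CST2, BCAT1, CCDC195, SIRPD and IL4I1 completed the 12 highest protein-coding genes.

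Of 34 measured NF-kB and cytokine genes, 31 were higher with CRABP1 in FTC-133, 20 of them by at least 2-fold and 0 lower by 2-fold, with a median log2 ratio of 1.35 at percentile 100 of matched random lists. Among 35 type I interferon response genes, 34 were higher and 13 passed 2-fold, with a median of 0.76; IFITM1 had a log2 ratio of 2.12, MX1 1.98 and IFI6 1.82. Antigen presentation genes had a median of 0.48, with HLA-DRA at 1.69 and CD74 at 1.07. ATF4 and amino acid response genes (median 0.58, TRIB3 at 1.13) and cholesterol genes (0.50, ACAT2 at 1.26 and MVD at 1.03) also stood apart above. Immediate early genes had a median of 0.30, with IER3 at 0.99 and BTG2 at 0.92, and extracellular matrix genes 0.16, with BGN at 4.05 and COL18A1 at 1.32.

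Genes lower in FTC-133 with CRABP1 included CD24, a surface glycoprotein, at 91.0 and 14.3 TPM (6.38-fold lower, 5.56 to 7.36), and CA9, a hypoxia-induced carbonic anhydrase, at 66.2 and 13.3 TPM (4.97-fold lower, 4.08 to 6.13). CGB5 had about 54 reads with vector and 0 with CRABP1. TMPRSS15, PPP1R14A, GPR183, ZNF114, MAGEA4, MYBPH, TENT5C, IGFL3 and TMPRSS11F were the others of the 12. Of 33 hypoxia and glycolysis genes 29 were lower (median -0.48), with the glucose transporter SLC2A1 at -1.68, while SLC2A3 and ADM were higher at 1.45 and 1.21. Heat shock genes had a median of -0.31 with HSPA1B at -0.79 and HSPB1 at -0.61, YAP/TAZ targets -0.16 with IGFBP3 at -1.74 and GADD45A at 0.84, and Wnt targets -0.17 with BMP4 at -1.42 and WNT7B at -0.91. G2/M genes were lower in 26 of 30 cases, by a median of -0.12 and with 0 past 2-fold, and mesenchymal genes had a median of -0.09, with S100A4 at -1.78 and POSTN at 1.59. Among marks of RNA quality, 5 structured RNAs had a median of 0.96, with RNU4-2 at 1.88 and RNU1-1 at -1.70, each from 2 reads in one library and 0 in the other. The signal recognition particle RNAs RN7SL1 and RN7SL2 were at 1.14 and 0.96, and in 8505C, where 3 members were too few to place, at 0.79 and 1.20. With means the YAP/TAZ, Wnt, mesenchymal and structured RNA lists were inside the range of random lists, as were Wnt targets at 5 TPM and with a pseudocount of 0.1.

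By the 2-fold rule, 1198 of 19899 genes were higher and 979 lower in FTC-133. Most were short or rarely read: of 12767 protein-coding genes with at least 20 reads, 263 were higher and 187 lower, and among 3650 genes under 20 reads the counts were 742 and 674. In 20 sets of Poisson draws from the pooled libraries, counting error alone gave 711 to 826 genes past 2-fold, and 0 to 3 among the protein-coding genes. In total 15 of 46 lists stood apart, 9 above and 6 below, where random lists of unrelated genes give 2.3. Members of a list can vary together, so that value does not measure chance for these lists. With list means in place of medians the number was 10.

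In 8505C, genes of amino acid supply were higher with CRABP1. CHAC1, a glutathione-degrading enzyme induced by ATF4, was at 1.44 and 19.0 TPM (13.2-fold, 7.88 to 24.2). The cystine transporter SLC7A11 was 3.62-fold higher (3.32 to 3.94), the neutral amino acid transporter SLC7A5 3.08-fold (2.86 to 3.32), the serine synthesis enzyme PSAT1 2.72-fold (2.54 to 2.93) and asparagine synthetase ASNS 5.72-fold (2.83 to 13.4). Of 26 ATF4 genes 23 were higher and 7 passed 2-fold, with a median log2 ratio of 0.58. RNASE10, FABP4, CHAD, S100A3, TAC4, NPIPB6 and LUM were the remaining highest genes.

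Proliferation genes were slightly higher in 8505C: all 30 G1/S and replication genes were above 0 (median 0.29, E2F2 at 0.82 and CDT1 at 0.66), as were 29 of 30 G2/M genes (0.19, CDK1 at 0.41) and 30 of 31 DNA repair genes (0.25, FANCD2 at 0.50), with 0 past 2-fold in these lists. Cholesterol genes had a median of 0.27 with HMGCS1 at 0.85, NRF2 genes 0.19, YAP/TAZ targets 0.15 with IGFBP3 at -0.73 and CCN2 at 0.68, and immediate early genes 0.13. Cell cycle inhibitors and D cyclins (0.16), MAPK output genes (0.12) and fatty acid genes (0.13) also stood apart above. With means the NRF2, immediate early, cell cycle inhibitor and MAPK output lists were inside the range of random lists.

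Inflammatory genes were lower in 8505C with CRABP1. All 25 measured NF-kB and cytokine genes were below 0, 6 by at least 2-fold, with a median of -0.62. The complement component C3 was at 16.7 and 2.30 TPM (7.27-fold lower, 5.87 to 9.08), the chemokine CXCL2 at 30.6 and 9.31 TPM (3.29-fold lower, 2.51 to 4.35) and C15orf48 at 18.9 and 1.68 TPM (11.2-fold lower, 6.21 to 22.2). MCCD1 had about 343 reads with vector and 0 with CRABP1. MAGEC2, SLC16A9, PDZK1IP1, G0S2, PAGE1, SLC6A14, BLOC1S1 and CD200 made up the other lowest genes. Hypoxia and glycolysis genes were below 0 in 32 of 34 cases (median -0.24, CA9 at -0.99 and HK2 at -0.82). Epithelial junction genes had a median of -0.22 with DSP at -1.16, extracellular matrix genes -0.15 with LAMB3 at -1.44, interferon genes -0.15 with SAMD9L at -0.79, antigen presentation genes -0.11 and mesenchymal genes -0.13 with LOX at -0.72. Thyroid tumour markers (-0.14), apoptosis regulators (-0.07) and nuclear oxidative phosphorylation genes (-0.05) also stood apart below. Beside these, ribosomal protein genes had a median of -0.07, housekeeping genes -0.08, replication-dependent histones -0.22, 5 fibroblast markers 0.46 and 5 endothelial markers -0.55, each standing apart. With means, of all lists in this paragraph only the NF-kB, hypoxia, epithelial and extracellular matrix lists stayed outside the range of random lists; the interferon, antigen presentation and mesenchymal lists were inside it at 5 TPM too.

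By the 2-fold rule, 649 of 17561 genes were higher and 715 lower in 8505C, of which 568 and 598 had under 20 reads. Counting error alone gave 628 to 707 genes past 2-fold in Poisson draws. Of 12010 protein-coding genes with at least 20 reads, 29 were higher and 60 lower, against 0 to 5 in all in the draws. In total 27 of 44 lists stood apart, 12 above and 15 below, where random lists of unrelated genes give 2.2. That value again does not measure chance for lists whose members vary together. With list means in place of medians the number was 11.

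**Figure D1:**
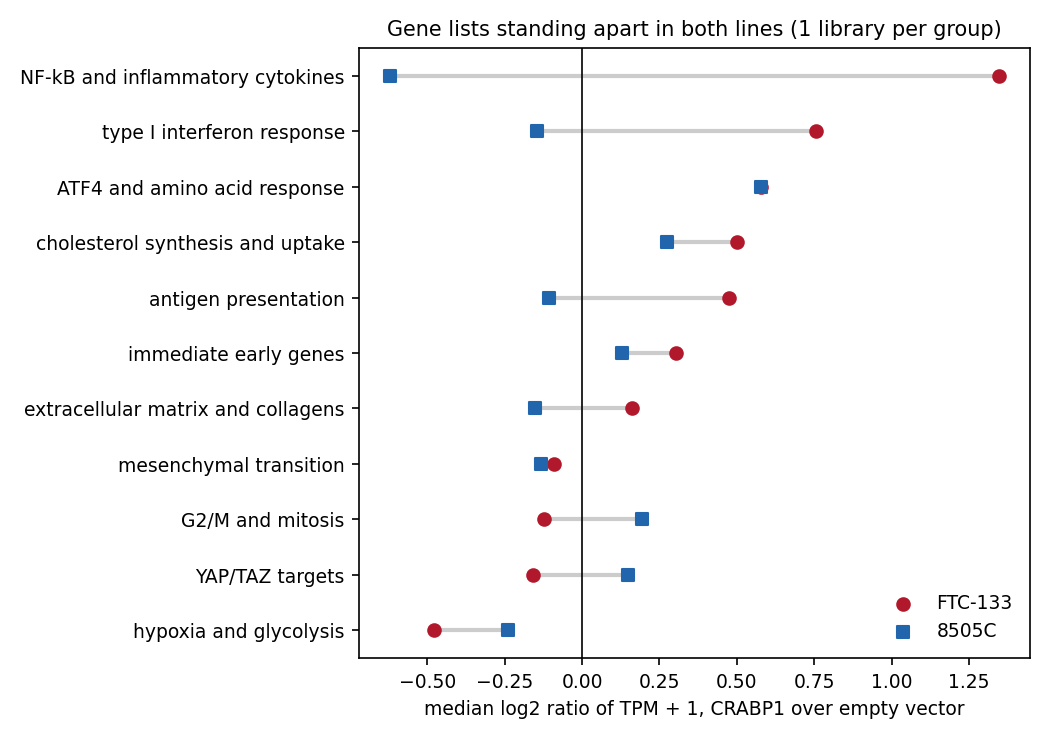
Median log2 ratio of TPM + 1 (x axis), CRABP1 over empty vector, for the 11 gene lists that stood apart in both lines (y axis). Circles are FTC-133 and squares 8505C, each from 1 library per group; the NF-kB list lies at 1.35 in FTC-133 and -0.62 in 8505C, and the ATF4 list at 0.58 in both.

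Over both lines, ATF4, cholesterol and replication genes were higher with CRABP1 and hypoxia genes lower by camera with the preset correlation. At that setting the p-values rest on the spread among genes, not on the 2 lines as replicates. The median over members of the mean log2 ratio was 0.60 for ATF4 genes (adjusted p = 1.63e-13), 0.44 for cholesterol genes (adjusted p = 1.68e-10), 0.20 for G1/S genes (adjusted p = 4.52e-06), 0.20 for DNA repair genes (adjusted p = 7.43e-06) and -0.42 for hypoxia and glycolysis genes (adjusted p = 9.18e-17). In FTC-133 alone the G1/S and DNA repair medians, 0.09 and 0.13, were inside the range of random lists, at percentiles 78.7 and 86.8, so these 2 results rest mainly on 8505C. With an estimated correlation each of these 5 lists had an adjusted p = 0.976. In all, 12 lists passed, the others being type I interferon (median 0.41, adjusted p = 0.000454), immediate early genes (0.14, adjusted p = 0.00435), cell cycle inhibitors and D cyclins (0.17, adjusted p = 0.0146), fatty acid genes (0.12, adjusted p = 0.0218) and antigen presentation (0.17, adjusted p = 0.0383) upward, and epithelial (-0.13) and mesenchymal genes (-0.07, adjusted p = 0.0215 for both) downward. Antigen presentation no longer passed with a pseudocount of 0.1 (adjusted p = 0.0670) or at 5 TPM (0.0731), nor did fatty acid genes at 5 TPM (0.0856). In FTC-133 alone the epithelial, fatty acid and cell cycle inhibitor medians were inside the range of random lists. With an estimated correlation 0 of the 12 passed, with adjusted p from 0.976 to 0.991, an estimate that rests on 1 residual degree of freedom and also missed a raised list in simulation. The simulated genes varied independently, so the simulation does not show that the preset holds for lists whose members vary together. Without the term for cell line as a block, 5 lists passed: hypoxia, cholesterol, ATF4, G1/S and DNA repair. The interferon and antigen presentation lists had medians of opposite sign in the lines.

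Genes with the same direction in both lines included SLC7A5 at log2 ratios of 0.85 in FTC-133 and 1.60 in 8505C, the cholesterol synthesis enzyme HMGCS1 at plain TPM ratios of 2.02 and 1.81, PSAT1 at log2 ratios of 0.78 and 1.44, PHGDH at log2 ratios of 0.79 and 0.75, and PDGFA at 1.26 and 0.78. HES7, ADM2, KRT34, MYEOV, HES4 and ARIH2OS were also among them. Lower in both were PAGE1, a cancer-testis antigen, at -1.61 and -1.65, CA9 at -2.23 and -0.99, the receptor KIT at -0.70 and -1.21, and IGFBP3 at -1.74 and -0.73, with PPFIA4, CDK18, GFRA1, CHMP4C, COX7A1, ADAMTS3, VASN and COLEC12. By limma, CRABP1 itself was the 1 gene of 19513 that rose, with a log2 difference of 8.83 (SE 0.174, higher in both lines, adjusted p = 0.0432), and 923 genes had an unadjusted p under 0.05, where chance gives 976. That call was lost with a pseudocount of 0.1, no filter, median-ratio scaling, no trend or no block, where the smallest adjusted p lay between 0.0949 and 0.844, and in simulation the test recovered 0% of 2-fold changes unless 16-fold and 64-fold changes were present too. Adjusted over the list alone, 16 of 27 ATF4 genes and 1 of 24 cholesterol genes passed, against 0 of either over all genes tested. That adjustment was made within each list, with no correction for the number of lists, and no other list had a member that passed. Both lists had already stood apart in these same libraries, so these passes are not separate support.

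The ratios of the 2 lines were nearly unrelated across genes, with Pearson's r of 0.029 and Spearman's rho of 0.025 over 19512 genes without CRABP1, which are not independent replicates. Among 15579 genes other than CRABP1 measured in both lines, 93 were higher and 84 lower by 2-fold in both, where independent lists give 14.4 and 12.4. In opposite directions there were 75 and 60 genes, 135 in all, where independent lists give 16.1 and 11.1. The values for independent lists assume that every gene passes 2-fold equally often. Under 20 reads, 20.33% of genes were higher and 18.47% lower in FTC-133, and 18.96% and 19.97% in 8505C. Over all genes the shares were 6.02% and 4.92% in FTC-133 and 3.7% and 4.07% in 8505C. The excess over independent lists, seen in opposite directions too, therefore does not measure a shared response. Among 11446 protein-coding genes with at least 20 reads in each pair, CRABP1 again left out, 0 were higher in both, 1 (PAGE1) was lower in both, 9 were higher in FTC-133 and lower in 8505C where independent lists give 0.61, and 0 went the reverse way. The 9 were C1R, C3, CCL2, CD200, CEMIP, CXCL1, CXCL2, GFPT2 and LAMB3. These counts use TPM + 1. In the reverse direction the plain TPM of PSG5 was 2.18-fold lower in FTC-133 (1.56 to 3.08) and 2.09-fold higher in 8505C (1.81 to 2.42), but its log2 ratio of TPM + 1 in FTC-133, -0.85, was short of 2-fold. Log2 ratios were -0.77 and 0.90 for PSG6, IGFBP5 -0.72 and 0.72, MPP7 -0.77 and 0.68, and NPR3 -1.08 and 0.67.

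**Figure D2:**
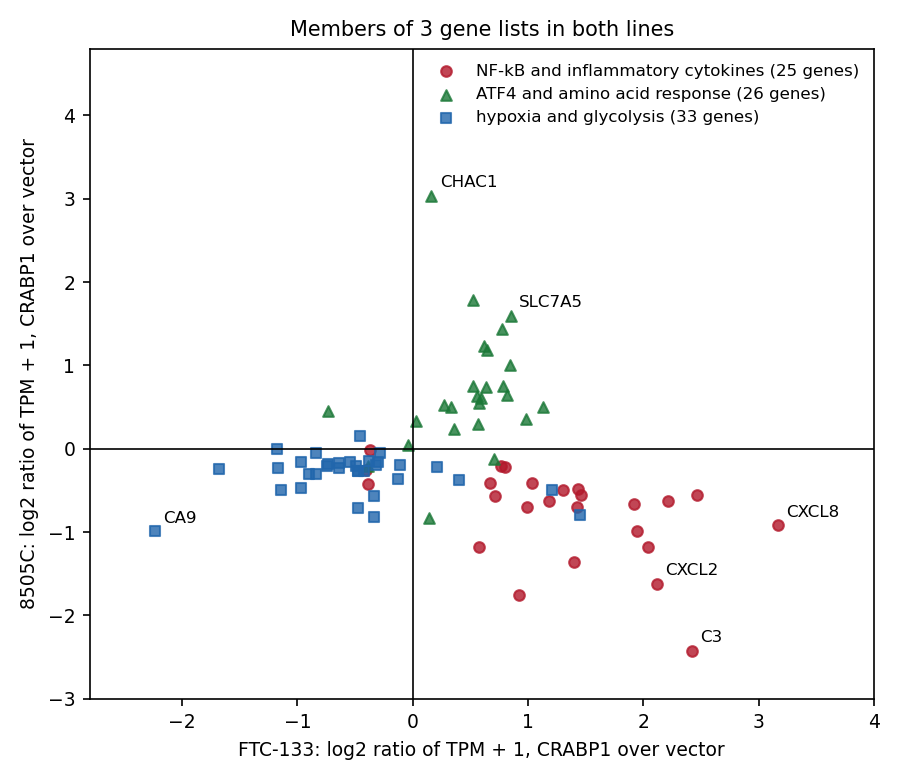
Log2 ratio of TPM + 1, CRABP1 over vector, in FTC-133 (x axis) and 8505C (y axis); each point is a gene measured in both lines, with 1 library per group. Of 25 NF-kB genes 22 were higher in FTC-133 and lower in 8505C, of 26 ATF4 genes 21 were higher in both, and of 33 hypoxia and glycolysis genes 27 were lower in both.

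Genes of retinoid handling differed little in 8505C and somewhat in FTC-133. In FTC-133 the retinol uptake receptor STRA6 was at 1.70 and 8.82 TPM (log2 ratio 1.86), ALDH1A3 had a ratio of 0.75 and DHRS3 of -0.78, and the 17 measured members had a median of 0.27 at percentile 98.6; their mean lay inside the range of random lists, at 96.2. In 8505C the median of 15 members was -0.075 at percentile 6.56, inside the range of random lists, with CRABP2 at 0.71 and DHRS3 at -0.61. Retinoic acid target genes had a median of 0.02 over 30 members in FTC-133, inside the range of random lists and of -0.05 with median-ratio scaling, where RARB, itself a retinoic acid receptor, was at 40.9 and 17.2 TPM (-1.20) and ELF3 at 1.18. In 8505C 17 of 23 were lower, with a median of -0.25 at percentile 0.02, BTG2 at -1.02, KLF4 at 0.88 and RARB at -0.11; their mean was inside the range of random lists, at 10.9. Receptors and cofactors had medians of -0.02 and -0.07, inside the range of random lists. No member of these lists passed limma, either over all genes or adjusted over the list alone, where the count was 0. By camera over both lines, retinoic acid targets went downward and did not pass at the preset correlation (adjusted p = 0.105). They passed at a mean of at least 5 TPM (adjusted p = 0.0478) but not with an estimated correlation (adjusted p = 0.976).

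Thyroid differentiation genes had medians of 0.23 over 11 members in FTC-133 and -0.02 over 7 in 8505C, both inside the range of random lists. The mean in 8505C, 0.04, had the opposite sign to the median. In FTC-133 the thyroid transcription factors PAX8 and FOXE1 had log2 ratios of 0.51 and 0.84, and NKX2-1 was at 44.7 and 17.7 TPM (-1.29). HHEX was at 0.13, DIO2 at 0.32 and THRB at 0.23. In 8505C NKX2-1 was at 118 and 114 TPM, and the largest ratio was that of HHEX at 0.30.

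The 2 lines themselves differed far more than the transfections. MMP1, an interstitial collagenase, was at 10.6 TPM in FTC-133 and 13980 TPM in 8505C with vector (1316-fold, 1095 to 1595). GDA, LIMCH1, STMN3, CDH5, ESM1, SMOC1, KRT14, PERP, TM4SF18, MSLN and MYL9 were also far higher in 8505C. The retrotransposon-derived gene PEG10 was at 689 TPM in FTC-133 and 0 in 8505C, and the secreted phosphoprotein SPP1 at 804 and 4.40 TPM. LCP1, CD70, MT1E, COL1A2, THY1, PAGE2, ADGRL4, COL1A1 and CTAG2 were also far lower in 8505C. PAX8 was at 100.1 TPM in FTC-133 and 0.240 in 8505C, and NKX2-1 at 44.7 and 118 TPM.

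By limma, 6877 of 19513 genes differed between the lines, 2542 higher and 4335 lower in 8505C. Without the filter on low values the number was 1182 of 36025. The vector and CRABP1 libraries of a line acted as replicates here and are not stated to be separate cultures. These p-values therefore measure only the spread between these libraries. Between the vector libraries alone, 2362 of 19470 genes were higher and 4208 lower by 2-fold; the median log2 ratio of all genes was -0.17 as deposited and -0.08 with median-ratio scaling. By camera 12 lists passed with the preset correlation, with the median of the vector libraries given first: ATF4 (-1.27, adjusted p = 1.62e-05), interferon (-1.37, adjusted p = 0.00164), NF-kB (-0.28, adjusted p = 0.0284) and mesenchymal genes (-1.25, adjusted p = 0.0396) lower in 8505C. Higher were MAPK output (0.79, adjusted p = 0.000772), ribosomal protein (0.22, adjusted p = 0.000612) and receptor tyrosine kinase genes (0.82, adjusted p = 0.0347). Epithelial (0.64), YAP/TAZ (0.20) and retinoic acid receptor genes (0.48) were higher with an adjusted p = 0.0137 each, and G2/M genes (0.07) and histones (0.78) with an adjusted p = 0.0180 each. With a mean of at least 5 TPM the G2/M (adjusted p = 0.0535), histone (0.246) and receptor tyrosine kinase lists (0.343) no longer passed, nor did mesenchymal genes without the term for transfection (0.0791). The G2/M, NF-kB, YAP/TAZ and ribosomal protein medians between the vector libraries were inside the range of random lists. With an estimated correlation 0 passed, with adjusted p of 0.915 or 0.966 for these 12. At the preset the camera p-values again rest on the spread among genes.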

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

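Tests of explanations by GC content, labels, cultures and scaling were chosen after the results were seen, although median-ratio scaling itself had been set beforehand, and those on read counting error before. The items below had log2 ratios of opposite sign in FTC-133 and 8505C with CRABP1; with 1 library per group the difference was not tested. For the NF-kB list the median log2 ratio was 1.35 in FTC-133 and -0.62 in 8505C, a difference of -1.97. The corresponding differences, 8505C minus FTC-133, were -0.90 for type I interferon genes, -0.58 for antigen presentation, -0.31 for extracellular matrix genes, 0.32 for G2/M genes and 0.31 for YAP/TAZ targets. With means in place of medians, interferon (percentile 6.51) and antigen presentation (8.91) in 8505C and YAP/TAZ targets in FTC-133 (3.42) were inside the range of random lists, the first 2 also at 5 TPM. Single genes differed by -4.85 for C3, -3.74 for CXCL2, -3.57 for CD200, -3.21 for CXCL1, -2.98 for CEMIP, -2.75 for CCL2, -2.63 for LAMB3, -2.30 for GFPT2 and -2.11 for C1R.

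For the NF-kB pattern, read counting error was argued against by the members' intervals: at least 79.4% excluded equality on the side of the pattern in each line. Bias from GC content or gene length was argued against as the whole cause, since the median was still at least 0.60 on that side once both trends were removed. Swapped labels in 8505C were excluded by about 2706 CRABP1 reads in the library labelled CRABP1 and 0 in the other. A difference between cultures unrelated to CRABP1 cannot be told apart from an effect of CRABP1, because each group held 1 library. A response that depends on the cell line may also account for it and was not tested.

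For lower hypoxia genes and higher ATF4 and cholesterol genes in both lines, at least 77.8% of members excluded equality on the side of the pattern in each list and line, against read counting error as the cause. The medians on that side were at least 0.23 once GC and length trends were removed and at least 0.25 with median-ratio scaling, against either as the whole cause. A difference between cultures unrelated to CRABP1, such as in density or medium, may account for the pattern and cannot be told apart from CRABP1 with 1 library per group. RN7SL1 and RN7SL2 were higher with CRABP1 in both lines; whether RNA quality or library preparation differed was not tested, and that explanation stays open. An effect of CRABP1 stays open in the same way.

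For genes past 2-fold, read counting error may account for part of the counts. Among genes under 20 reads, 7.6% in FTC-133 and 5.9% in 8505C had an interval that excluded equality. The bound set beforehand was 7.5% in each line, so the test did not decide. In the Poisson draws, counting error alone put 689 to 789 genes of this class past 2-fold in FTC-133 and 604 to 692 in 8505C. Among genes of known length 1412 and 1166 were observed, so the draws gave part of these counts and not all. Among protein-coding genes with at least 20 reads the shares with such an interval were 56.0% and 39.4%. These shares, like those under 20 reads, cover all genes of a class at any fold, not only those past 2-fold. In the Poisson draws 0 to 3 protein-coding genes of this class passed 2-fold in FTC-133 and 0 to 5 in 8505C, where 450 and 89 were observed. That argues against counting error as the cause of most of them. Differences between cultures stay open.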

How the results depend on the processing

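Restriction to protein-coding genes with at least 20 reads and removal of GC and length trends were chosen after seeing the data. Counts by the 2-fold rule are given in the order FTC-133 higher, FTC-133 lower, 8505C higher, 8505C lower, both higher, both lower, opposite, and 8505C over and under FTC-133 with vector. At a mean of at least 5 TPM they were 354, 237, 97, 121, 9, 6, 23, 1260 and 1924. With a 1.5-fold threshold they were 2598, 1928, 1297, 1341, 249, 194, 399, 3905 and 6323. Counts over both lines leave out CRABP1, and counts per line include it. Among protein-coding genes with at least 20 reads they were 263, 187, 29, 60, 0, 1, 9, 1280 and 2121. Fewer or more genes enter these counts by construction. Without a filter, the counts that moved were 1117 and 1162 in 8505C, 182 and 152 in both lines and 274 in opposite directions. A pseudocount of 0.1 gave 235 in opposite directions. Without mitochondrially encoded genes the counts were 148 and 138 in both lines and 235 in opposite directions; rescaling then raised all other TPM values, so that 16811 genes entered in both lines in place of 15579. Median-ratio scaling moved none of these counts by over 1.5 times. For CRABP1 over both lines, limma called 0 genes with a pseudocount of 0.1, no filter, median-ratio scaling, no trend or no replicate block; for 8505C against FTC-133 it called 1182 without a filter. By camera 0 lists passed with an estimated correlation in either comparison, and 5 without the replicate block for CRABP1. With means in place of medians 11 lists stood apart in 8505C in place of 27, and 10 in FTC-133 in place of 15; the cause was not tested. Of the alternatives for list medians 498 kept their side of the range, 26 lost it, 8 gained it and 0 changed sign among lists standing apart. NF-kB, hypoxia, ATF4 and cholesterol medians stood apart in both lines under each alternative run for lists. With means, 16 lists in 8505C were inside the range: interferon (percentile 6.51), antigen presentation (8.91), retinoic acid targets (10.9), thyroid tumour markers, mesenchymal genes, cell cycle inhibitors, apoptosis regulators, MAPK output, immediate early, nuclear oxidative phosphorylation, NRF2, ribosomal protein, histone, housekeeping, fibroblast and endothelial genes. In FTC-133 the 5 were YAP/TAZ targets (3.42), retinoid metabolism (96.2), mesenchymal genes, Wnt targets and structured RNAs. At 5 TPM interferon, antigen presentation and mesenchymal genes in 8505C and Wnt targets in FTC-133 were inside it, the last also with a pseudocount of 0.1. Leaving out a line leaves no residual degrees of freedom, so no test was run and the values per line stand in its place. No paired analysis by replicate number was possible because each group held 1 library. Depth limits genes under 20 reads most.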

Other observations

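The genes below were singled out after their values were seen. Some protein-coding genes had at least 20 reads in one library of a line and 0 in the other. In FTC-133 RXFP2 had about 33 reads and CLSTN2 28 with CRABP1 and 0 with vector, whereas GHR had 24 and ANXA8, which has near-identical copies, 20 with vector and 0 with CRABP1. In 8505C FABP4 had about 20 reads with CRABP1 and 0 with vector, and MCCD1 343 with vector and 0 with CRABP1. In FTC-133 with vector MCCD1 had about 3 reads. The mitochondrial complex I gene NDUFV2 had a log2 ratio of -1.10 in 8505C and 0.56 in FTC-133, while the median of nuclear oxidative phosphorylation genes was -0.05 and 0.14.

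Of the lists fixed beforehand, 16 of 46 stood apart between the vector libraries. ATF4 genes were lower in 8505C than in FTC-133 in 25 of 27 cases, with ALDH1L2 at a log2 ratio of -5.04 and CHAC1 at -4.39. Among interferon genes 27 of 35 were lower, with IFI44 at -5.91 and IFI27 at -4.83. MAPK output genes were higher in 17 of 22 cases, with EPHA4 at 2.95 and SPRY1 at 2.64. NRF2 genes had a median of -0.46, with HMOX1 at -5.50.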
